A study of Gallus gallus with 5 samples.

How the data were processed

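RNA was sequenced from the livers of 5 broiler breeder hens, the parent stock of meat chickens. Of these, 2 hens had been fed without limit (FF) and 3 had been fed a restricted allowance (RF), and the feeding groups were set up when the hens reached 38 weeks of age. Each library came from a separate hen, and the labels' hen numbers differ between all 5. The extraction protocol in the labels names 3 hens per group, and a further FF hen was not analysed here. Libraries kept the strand of the RNA, and every RNA sample had an integrity number above 8, per the labels' protocols.

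The deposited table held estimated counts per gene symbol, one column per hen, with no normalization by the authors apparent in the column totals. Of its 6286 entries, 51 had a value that was not whole (0.811%), so the estimated counts were rounded to whole numbers before testing. FastQC, TopHat2 2.0.13, Cuffdiff 2.2.1 and edgeR are named with the chicken genome build galGal4, per the submitters' processing notes, which assign no role or order to them. The annotation, the handling of reads that fit several genes, and whether the counting used strand are not given in the sources used here. Values of genes with close paralogues (THRSP and THRSPB, MT3 and MT4, AMY1A and AMY2A, the cytochrome P450 genes and the globins) and of overlapping genes are therefore uncertain. In the table, 10 symbols had been turned into calendar dates, 711 entries were microRNAs, and 1240 entries, 554 of them not microRNAs, were listed at 0 in all 5 hens. Genes that livers normally express at high level were among these, ALB and APOV1 included, so a 0 was read only as listed at 0 and not as absence of the transcript.

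Library totals ranged from 2666609 to 4622392 estimated counts. Genes were kept for testing by edgeR's filterByExpr with a minimum count of 10, which left 4309 genes and dropped 1977. Counts were scaled with the trimmed mean of M values (TMM) and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided, feeding group as the single term) in R 4.3.3. Adjusted p-values follow Benjamini-Hochberg with a threshold of 0.05, and log2 fold changes are FF over RF with their standard errors. Expression is given as CPM (counts-per-million of the TMM-scaled library size), as mean ± SD over the hens of a group. The biological coefficient of variation between hens of a group was 32.4%.

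Gene lists were tested with camera in limma 3.58.1 on log2 CPM, with the correlation between genes preset to 0.01 and Benjamini-Hochberg adjustment over the 38 lists that had at least 5 tested members. Camera with an estimated correlation and fry were run beside it. The 40 lists (27 pathways and 13 cell types) were written from textbook knowledge, and the groups, tests, lists, rule for named genes and alternative settings were fixed before the data were examined. Within a list, members were also counted when adjusted over the list alone, which does not control error across the 40 lists. The text names genes by 3 rules. Among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between groups, up to 10 with the largest change in each direction were named. From each list, up to 4 members past the threshold were named or, where none passed, the 2 with the smallest p as values only. A set of 21 key genes of egg yolk, lipid and endocrine function was always given where measured. Genes outside these rules are marked as chosen after their values were seen, except where they are named only as called by an alternative setting, and some genes that fell under the rules are not reported here.

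The steps were tested on simulated data, in 10 data sets of 4309 genes with 200 genes changed by known folds. Counts were drawn from each gene's mean over these 5 libraries, the library sizes, and the dispersion typical of a gene's abundance. The dispersion came from the fit of the real FF and RF hens, so the simulation followed that fit. For the FF against RF comparison, the edgeR quasi-likelihood test recovered 14.6% of genes changed 2-fold, 85.7% of those changed 4-fold and 96.3% of those changed 8-fold, and 4.14% of its calls were false. On the same data DESeq2 recovered 18.1%, 84.8% and 95.2%, with 8.92% of its calls false. The mean number of calls was 133 by the quasi-likelihood test and 141 by DESeq2, against 2 and 79 in the real data. The 2 tests were thus close in the simulation and far apart in the real data, so these recovered shares do not carry over. The simulation gave no gene a spread of its own and held no hen that stood apart, so recovery in the real data may be lower. For example, G0S2 and DIO3 did not pass in the real data at log2 fold changes of 4.27 and -6.38 (edgeR quasi-likelihood, adjusted p = 0.136 for each).

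Alternatives were DESeq2 size factors, upper quartile scaling, library totals alone, no filter on low counts, a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, the edgeR likelihood ratio test, limma-voom, a threshold of 0.1, an added limit of 1 on the absolute log2 fold change, the replicate number as a block, removal of the 10 most abundant genes, and leaving out each hen in turn. The RefSeq gene table of the GRCg7b assembly, a later build than galGal4, was used only for names and for which genes are neighbours, and 4221 of the 4309 tested genes were matched to it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.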

Results

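Liver transcriptomes were measured by RNA sequencing in 2 hens fed without limit (FF) and 3 hens on restricted feed (RF), to ask how feeding level altered expression in the liver, which makes the egg yolk precursors and most of the body lipid of the laying hen. Library totals were 4622392 (FF1) and 2666609 (FF2) estimated counts in FF and 4493687 (RF1), 3357844 (RF2) and 4471414 (RF3) in RF. The yolk precursor vitellogenin (VTG1) had the highest count of the table's entries in every hen, at 5.66% (RF2) to 10.1% (RF1) of the counts in the table, a ranking that leaves out liver genes listed at 0 (ALB and APOV1, for example). The 95% Wilson intervals of these shares, which cover counting error alone, reached no further than 0.0295 percentage points to either side. The FF2 library stood apart from the other 4. It lay at 44.5 on a first principal component holding 50.7% of the variance, where the others lay between -28.0 and -1.75, and its Pearson correlations with them across genes, which are not independent replicates, were 0.877 to 0.922. FF2 was also the library with the lowest total.

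BUB1 and AACS were higher in the livers of FF hens. BUB1, a kinase of the mitotic spindle checkpoint, stood at 106 ± 44.6 CPM (SD, n = 2) in FF and 4.02 ± 1.78 CPM (SD, n = 3) in RF, a log2 fold change of 4.70 ± 0.44 (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0346). AACS, which activates the ketone body acetoacetate for lipid synthesis in the cytosol, stood at 301 ± 80.4 CPM (SD, n = 2) in FF and 26.2 ± 9.24 CPM (SD, n = 3) in RF, a log2 fold change of 3.51 ± 0.38 (edgeR quasi-likelihood, adjusted p = 0.0482). In both genes the 2 FF hens lay above all 3 RF hens. These were the 2 of 4309 genes that passed, and 0 genes passed as higher in RF.

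Below that threshold, 403 genes had an unadjusted p under 0.05 (190 higher and 213 lower in FF), where 215 would be expected by chance and the 9 other splits of the hens into 2 and 3 gave 51 to 415. DESeq2 called 79 genes (31 higher and 48 lower in FF). FF and RF values did not overlap in 27.0% of genes (565 with FF above and 597 with FF below), where chance gives 20%. At an adjusted p under 0.1 by the edgeR quasi-likelihood test, 7 genes passed, and those beyond the first 2 that are named here were chosen after their values were seen. DHCR7, which catalyses the last step of cholesterol synthesis, INHBA, which encodes an activin and inhibin subunit, and the ubiquitin ligase WWP1 were higher in FF, at log2 fold changes of 1.97 ± 0.25, 3.68 ± 0.50 (4.29 without FF1 and 2.61 without FF2) and 1.77 ± 0.25. The secretin receptor SCTR was lower in FF, at -2.61 ± 0.37. The calls of both leading genes were lost, with their fold changes close to those above, when some single hens were left out. Without FF2, RF1 or RF2 the log2 fold change was 4.20, 4.53 and 4.53 for BUB1 and 3.22, 3.57 and 3.27 for AACS. Without FF2, RF1 or RF2, 0 genes passed by the edgeR quasi-likelihood test (311, 235 and 236 at an unadjusted p under 0.05), with adjusted p of 0.0883, 0.354 and 0.157 for BUB1 and of 0.103, 0.484 and 0.157 for AACS, and the filter of 5 CPM put AACS at 0.0515. Over all 17 alternatives the adjusted p ranged from 9.96e-18 to 0.354 for BUB1 and from 9.60e-14 to 0.484 for AACS (edgeR, limma-voom or DESeq2).

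**Figure D1:**
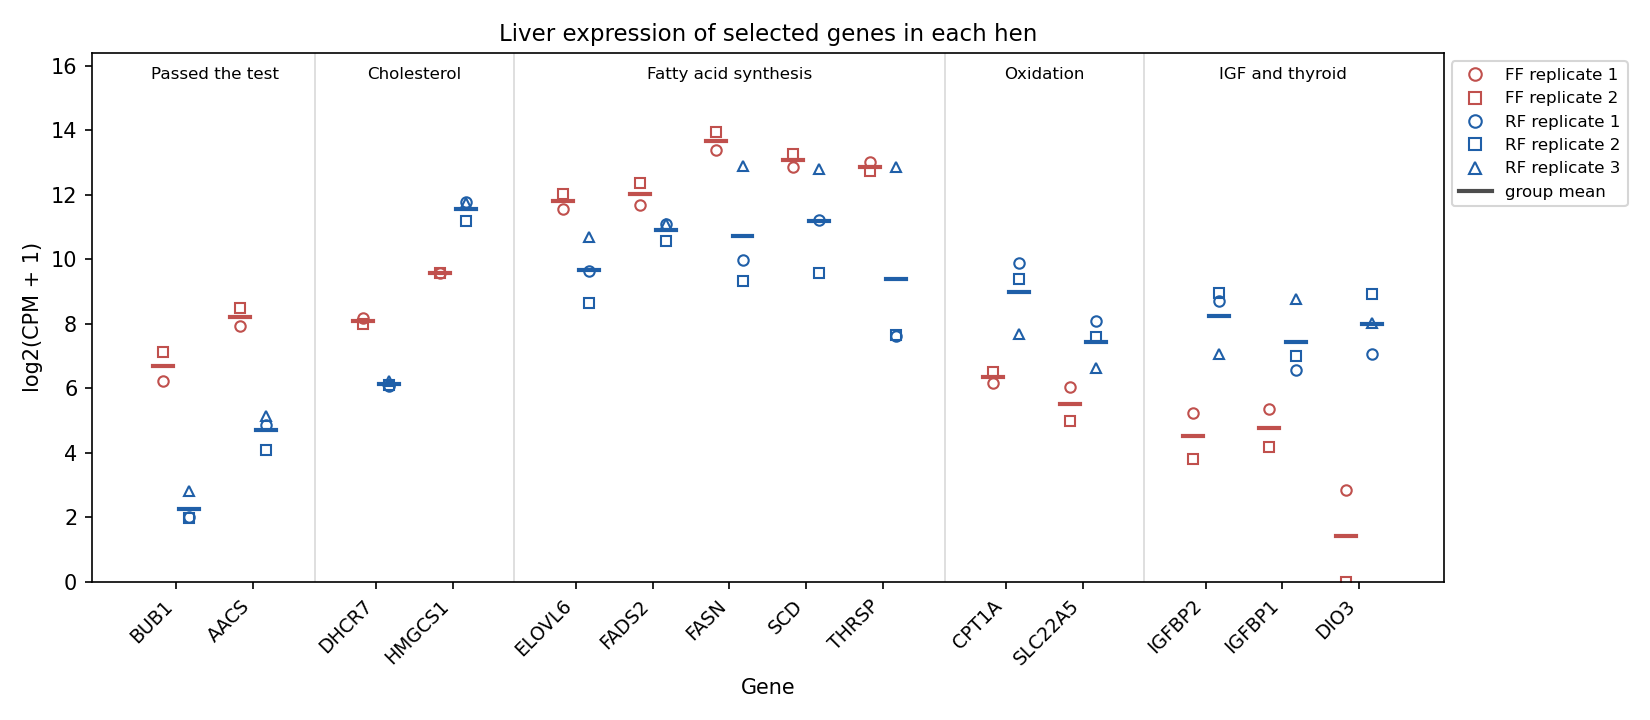
Expression of 14 liver genes in each hen, as log2 of CPM plus 1, with one open symbol per hen (FF red, n = 2; RF blue, n = 3) and a bar at each group's mean. BUB1 and AACS lay higher in both FF hens than in the RF hens, CPT1A lay lower, and RF replicate 3 lay near the FF hens in FASN, SCD and THRSP.

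Genes of cholesterol synthesis and uptake lay mostly higher in FF. Of 14 tested members 10 had a log2 fold change above 0, with a median of 1.24. By the edgeR quasi-likelihood test 0 passed over all genes, while adjusted over the list alone 8 passed as higher and 2 as lower. DESeq2 called 6 higher and 1 lower members, and 8 and 3 had an unadjusted p under 0.05 in edgeR. Among the higher members, DHCR7 stood at 272 ± 24.8 CPM (SD, n = 2) in FF and 69.6 ± 3.63 CPM (SD, n = 3) in RF. The lower members were HMGCS1 (log2 fold change -2.02 ± 0.35) and ACAT2 (-1.06 ± 0.35), named after their values were seen, which act at the first steps from acetyl-CoA. Of the nearest tested genes, all chosen after their values were seen, NIM1 next to HMGCS1 lay at -1.80 ± 0.47, and SEPP1 and PAIP1 farther out on either side at -0.46 ± 0.36 and -0.25 ± 0.30. Camera in limma placed the list above other genes (adjusted p = 0.00377), but the call was lost with adjusted p = 0.584 with an estimated correlation and at 0.231 without FF1 (limma, range over 10 alternatives 8.43e-04 to 0.584).

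As a group, fatty acid synthesis genes lay higher in both FF hens than in RF1 and RF2. Of 16 tested members 12 lay above 0 with a median log2 fold change of 0.82, and by the edgeR quasi-likelihood test 0 passed over all genes or adjusted over the list alone. An unadjusted p under 0.05 was found for 2 higher and 1 lower members (edgeR), and DESeq2 called 1 and 0. ELOVL6, which lengthens palmitate, stood at 1.92 ± 0.56 (2.59 without RF3), the desaturase FADS2 at 1.13 ± 0.36 and the fatty acid synthase gene FASN at 2.12 ± 0.96. The stearoyl-CoA desaturase SCD lay at 1.33 ± 0.78, ACACA, which makes malonyl-CoA, at 1.35 ± 0.74 and malic enzyme ME1 at 0.93 ± 0.96. The lipogenic nuclear protein THRSP was at 1.51 ± 1.39, ACLY, which makes cytosolic acetyl-CoA, at 0.26 ± 0.55, and their regulator SREBF1 at -0.22 ± 0.46. ACLY and SREBF1 changed sign without FF2, SREBF1 standing at -1.15 without FF1. The third RF hen differed from the others of its group, with FASN at 7619.7 CPM against 1001 in RF1 and 644 in RF2, and THRSP at 7524 against 198 and 199, while the FF hens lay at 10845 and 15948 for FASN and at 8235 and 6857 for THRSP. Camera in limma called the list higher in FF (adjusted p = 0.00531), with adjusted p = 0.595 with an estimated correlation and 0.231 without FF1 (limma, range over 10 alternatives 3.69e-08 to 0.595). Without RF3, 8 genes passed by the edgeR quasi-likelihood test, THRSP (log2 fold change 5.25) and FASN (4.03) among them, and ME1, SCD and ACACA lay at 2.94, 2.47 and 2.45.

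Among genes of triglyceride synthesis and lipid droplets, members that handle stored fat lay on both sides. Of 10 tested members 3 lay above 0, with a median log2 fold change of -0.52, and the camera test in limma gave an adjusted p of 0.459. By the edgeR quasi-likelihood test 0 passed over all genes, and adjusted over the list alone 2 passed as higher and 2 as lower. In edgeR 2 higher and 4 lower members had an unadjusted p under 0.05, and DESeq2 called 2 and 2. G0S2, an inhibitor of the lipase that breaks down stored triglyceride, was at 632 ± 263 CPM (SD, n = 2) in FF and 32.8 ± 22.6 CPM (SD, n = 3) in RF (4.27 ± 0.74 on the log2 scale). PLIN2, which coats lipid droplets and was named after its values were seen, was at 1.99 ± 0.52 (1.32 without FF2). The droplet proteins CIDEC (-2.54 ± 0.58) and CIDEA (-1.42 ± 0.39) were lower.

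Cell cycle genes lay slightly higher in FF as a group. Besides BUB1, which passed over all genes and also adjusted over the list alone, 28 of the other 31 tested members had a log2 fold change above 0, none above the 1.53 of CDK1 (named after its values were seen), and the median of the list was 0.65. Camera in limma called the list higher (adjusted p = 3.50e-05), with adjusted p = 0.608 with an estimated correlation and 0.409 without FF1 (limma, range over 11 alternatives 1.56e-10 to 0.608). The mean of its members, BUB1 included, was 0.68 in FF1 and 0.12 in FF2, relative to the mean of the 5 hens on the log2 scale. In RF1, RF2 and RF3 it was -0.71, -0.07 and -0.02. BUB1 was at 138 CPM in FF2 and at most 6.08 CPM in the RF hens. It therefore widens the small gap of FF2 from RF2 and RF3, and the larger contrast was that of FF1 with RF1. In FF1 the stellate cell and fibroblast markers (0.54) and the matrix genes (0.45) also stood highest of the 5 hens. In the GRCg7b annotation a long noncoding gene overlaps BUB1, and TMEM132B and a noncoding gene overlap AACS; none of these was among the tested genes.

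**Figure D2:**
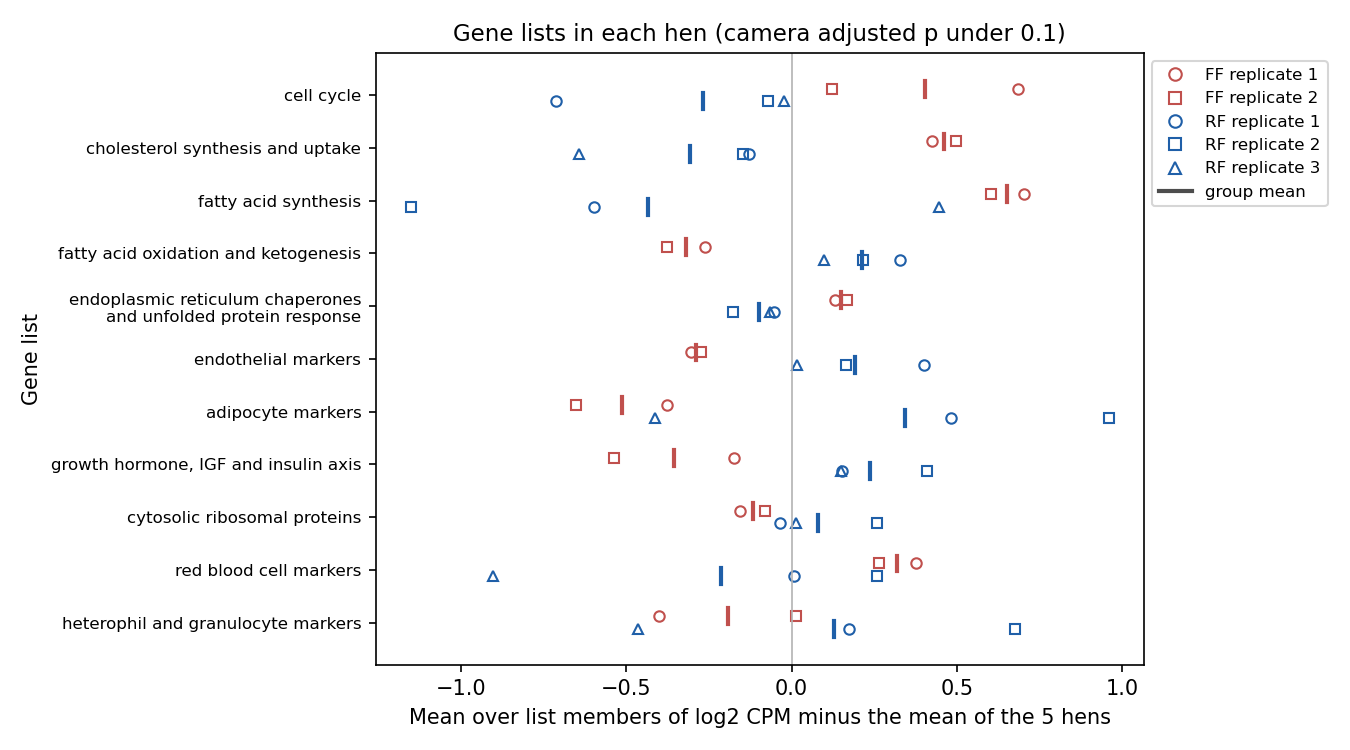
Gene lists in each hen for the 11 lists with a camera adjusted p under 0.1, as the mean over list members of log2 CPM minus the mean of the 5 hens, with one open symbol per hen (FF red, n = 2; RF blue, n = 3) and a bar at each group's mean. In fatty acid synthesis RF replicate 3 stood at 0.45, between the FF hens and the other RF hens.

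Several genes of fatty acid oxidation and ketone bodies lay lower in FF, though the list passed only in some alternatives. CPT1A, which admits long-chain fatty acids to the mitochondrion, was at 80.3 ± 12.4 CPM (SD, n = 2) in FF and 608 ± 373 CPM (SD, n = 3) in RF, a log2 fold change of -2.92 ± 0.65. Of 24 tested members 0 passed over all genes by the edgeR quasi-likelihood test, and adjusted over the list alone 4 passed as lower in FF. In edgeR 0 higher and 6 lower members had an unadjusted p under 0.05, and DESeq2 called 0 and 4. Those that passed over the list alone included CPT1A and, named after its values were seen, the carnitine carrier SLC22A5 (-1.96 ± 0.52, -2.61 without FF1). The list as a whole had 11 members above 0 and a median of -0.10, and camera in limma gave an adjusted p of 0.0583 but under 0.05 without RF1, RF2 or RF3 or with the replicate block.

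Genes of glucose supply and use did not pass as groups. PCK1, which commits precursors to gluconeogenesis, and its coactivator PPARGC1A lay at -2.83 ± 0.72 (-2.17 without FF1 and -3.95 without FF2) and -2.26 ± 0.70 (-1.64 without RF1). The list of gluconeogenesis and glycogen had 12 tested members, 7 of them above 0, a median of 0.03 and a camera adjusted p of 0.991 (limma). In glycolysis and hexose uptake (19 tested, 12 above 0, median 0.07, camera adjusted p 0.991, limma), PDK3 lay at 0.42 ± 0.36 and changed sign without FF2. Among bile acid and sterol genes (9 tested, 4 above 0, median -5.21e-04, camera adjusted p 0.459, limma), CYP7A1, the rate-limiting enzyme of bile acid synthesis, was at 285 ± 31.8 CPM (SD, n = 2) in FF and 94.9 ± 17.4 CPM (SD, n = 3) in RF (1.59 ± 0.28) and passed adjusted over the list alone. CYP8B1 lay at 1.28 ± 0.59 (2.12 without RF3).

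The growth hormone and insulin-like growth factor genes were led by binding proteins that lay lower in FF. IGFBP2 was at 24.8 ± 16.6 CPM (SD, n = 2) in FF and 347 ± 188 CPM (SD, n = 3) in RF and IGFBP1 at 28.5 ± 16.2 CPM (SD, n = 2) in FF and 219.8 ± 189 CPM (SD, n = 3) in RF. Their log2 fold changes were -3.78 ± 0.72 (-4.73 without FF1) and -2.93 ± 0.77 (-3.69 without FF1 and -1.94 without RF3). Of 20 tested members 5 lay above 0 with a median of -0.48. By the edgeR quasi-likelihood test 0 passed over all genes, and adjusted over the list alone 1 passed as higher (PRLR, 1.35 ± 0.38) and 3 as lower, the third being the cytokine signalling inhibitor CISH (-2.09 ± 0.56, -3.18 without FF1 and -1.47 without FF2). An unadjusted p under 0.05 was found for 1 higher and 5 lower members (edgeR), and DESeq2 called 0 and 3. PRLR and CISH were named after their values were seen, and camera in limma gave an adjusted p of 0.0591 but under 0.05 without RF1 or RF3 or with the replicate block. The growth hormone receptor GHR lay at 0.73 ± 0.39, and IGF1 was below the filter, with 4 and 2 estimated counts in the FF hens and 0 in each RF hen. LEPR was below it too, at 2 to 8 estimated counts.

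Of the thyroid hormone genes, DIO3 passed adjusted over the list alone as lower in FF. This gene, whose enzyme inactivates thyroid hormone, was at 3.08 ± 4.35 CPM (SD, n = 2) in FF and 292 ± 177 CPM (SD, n = 3) in RF. Its log2 fold change was -6.38 ± 1.11, -5.55 without FF2, and -13.1 without FF1, which leaves FF2 alone at 0 CPM. DIO2, which activates the hormone and did not pass, lay at 2.17 ± 0.67 (2.86 without FF1, 0.84 without FF2 and 2.78 without RF3). The thyroid list had 10 tested members, 6 above 0, a median of 0.60 and a camera adjusted p (limma) of 0.459 but under 0.05 with the replicate block. In the circadian clock list (16 tested, median 0.22, camera adjusted p 0.324, limma), ARNTL2 lay at 1.22 ± 0.51 (0.46 without FF2) and PER2 at 1.07 ± 0.53, at 1.76 without FF1 and -0.25 without FF2. In the glucocorticoid and fasting list (14 tested, median -0.07, camera adjusted p 0.459, limma), the neighbouring metallothionein genes MT3 and MT4 lay at -2.84 ± 0.86 (-3.66 without FF1 and -1.65 without RF2) and -2.49 ± 0.85 (-3.92 without FF1, -1.77 without FF2 and -1.72 without RF2).

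Yolk precursor expression showed no called difference between the feeding levels. VTG1 was at 69370.0 ± 9767 CPM (SD, n = 2) in FF and 80162 ± 25766 CPM (SD, n = 3) in RF (-0.21 ± 0.38 on the log2 scale), the yolk lipoprotein gene APOB at 0.08 ± 0.39 and the oestrogen receptor ESR1 at 0.21 ± 0.40, and each of these 3 changed sign when 1 or more single hens were left out. Of 17 tested yolk and oestrogen-responsive genes 7 lay above 0 (median -0.21, camera adjusted p 0.672, limma), with the retinol carrier RBP4 at -1.30 ± 0.44 (-1.88 without FF1) and the apolipoprotein APOA1 at 1.20 ± 0.43. Of 15 lipoprotein and lipid transport genes 8 lay above 0 (median 0.05, camera adjusted p 0.962, limma), with the fatty acid binding protein FABP5 at -2.07 ± 0.51. VTG2 and APOV1, which encodes apovitellenin, were listed at 0 in every hen.

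Endoplasmic reticulum chaperones lay above 0 in 24 of 35 tested members (median 0.20), and by the edgeR quasi-likelihood test 0 passed over all genes or adjusted over the list alone. DESeq2 called 3 higher and 0 lower members, and 7 and 1 had an unadjusted p under 0.05 in edgeR. HSPA5, the main chaperone of that compartment, was at 3193 ± 349 CPM (SD, n = 2) in FF and 1259.9 ± 232 CPM (SD, n = 3) in RF (1.34 ± 0.31), and its stress-induced partner CRELD2 lay at 1.21 ± 0.27. Camera in limma gave this list an adjusted p of 0.0583 but under 0.05 without FF2 or RF1 or with the filter of 5 CPM. The amino acid response list (20 tested, median 0.28, camera adjusted p 0.241, limma) had the transporter SLC38A2 at -0.97 ± 0.44 and the transporter SLC7A5 at 52.1 ± 31.6 CPM (SD, n = 2) in FF and 105 ± 21.7 CPM (SD, n = 3) in RF (a log2 fold change of -1.82 without FF1). Heat shock proteins (16 tested, median 0.10, camera adjusted p 0.672, limma) had HSP90AB1 at 0.87 ± 0.29 and HSPB1 at -0.51 ± 0.32. In amino acid catabolism and uric acid synthesis (27 tested, median 0.06, camera adjusted p 0.983, limma), the purine enzyme ATIC was at 3766 ± 145 CPM (SD, n = 2) in FF and 14543 ± 5573 CPM (SD, n = 3) in RF (-1.95 ± 0.44). The glycine decarboxylase GLDC lay at 1.44 ± 0.54 (2.06 without RF3).

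None of the housekeeping groups was called. Ribosomal proteins (51 tested, 14 above 0, median -0.16, camera adjusted p 0.0591 but under 0.05 without FF2 or RF1, limma) had RPS29 at -0.85 ± 0.30 and RPSA at -0.81 ± 0.31. In oxidative phosphorylation (34 tested, median 0.04, camera adjusted p 0.459, limma) NDUFA12 lay at 1.15 ± 0.47 (1.76 without FF1 and 0.07 without FF2) and COX6C at 0.56 ± 0.26. The proteasome (19 tested, median 0.16, camera adjusted p 0.459, limma) had PSMD1 at -0.69 ± 0.28 and PSMA7 at 0.60 ± 0.30. Autophagy and lysosome genes (22 tested, median -0.08, camera adjusted p 0.459, limma) had ATG3 at 0.65 ± 0.26 and HEXA at -0.79 ± 0.39 (-1.55 without FF1). Of the 126 tested genes of these 4 lists 0 passed over all genes or adjusted over the list alone by the edgeR quasi-likelihood test. An unadjusted p under 0.05 was found for 2 higher and 4 lower members (edgeR), and DESeq2 called 0 and 0.

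The list of xenobiotic metabolism and haem synthesis held 3 genes that lay lower in FF and passed adjusted over the list alone. They are named as members of that list, which does not give each a role in detoxification. By the edgeR quasi-likelihood test 0 of its 25 tested genes passed over all genes. An unadjusted p under 0.05 was found for 2 higher and 4 lower members (edgeR), and DESeq2 called 0 and 3. The 3 genes were CYP4V2 (-1.40 ± 0.27), CYP2C18 (-3.37 ± 0.70, -2.77 without FF1 and -4.44 without FF2) and, named after its values were seen, UGT8 (-1.18 ± 0.30). CYP2C18 stood at 173 ± 129 CPM (SD, n = 2) in FF and 1791 ± 834 CPM (SD, n = 3) in RF. That list had a median of -0.18 and a camera adjusted p of 0.672 (limma). In antioxidant defence (17 tested, median -0.12, camera adjusted p 0.705, limma), TXNRD1 lay at 0.66 ± 0.28 and its regulator NFE2L2 at 0.61 ± 0.28.

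Of 63 tested inflammatory and matrix genes 0 passed over all genes or adjusted over the list alone by the edgeR quasi-likelihood test. In edgeR 2 higher and 3 lower members had an unadjusted p under 0.05, and DESeq2 called 0 and 0. In acute phase and inflammation (21 tested, 5 above 0, median -0.35, camera adjusted p 0.104 but under 0.05 without RF1, limma), the inhibitor NFKBIA lay at -2.19 ± 0.87 (-0.71 without RF3) and the cytokine IL18 at -2.23 ± 0.91 (-0.98 without RF3). The interferon list (14 tested, median -0.37, camera adjusted p 0.547, limma) had the RNA sensors EIF2AK2 at 0.77 ± 0.26 and IFIH1 at 0.64 ± 0.29. In extracellular matrix and fibrosis (28 tested, median 0.17, camera adjusted p 0.459 but under 0.05 without FF2, limma), FBLN1 lay at -1.12 ± 0.30 and MMP2 at 0.98 ± 0.31.

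Marker lists of the cell types of liver tissue were not called between the groups by camera in the main test. By DESeq2, 1 cholangiocyte, 2 adipocyte and 1 hepatocyte marker were called as lower in FF. It called 0 endothelial and 0 stellate cell and fibroblast markers. Endothelial markers (9 tested, 1 above 0, median -0.50, camera adjusted p 0.0583 but under 0.05 without FF2, RF2 or RF3 or with the replicate block, limma) had KDR at -1.03 ± 0.36 and LYVE1 at -0.93 ± 0.39. Adipocyte markers (7 tested, 1 above 0, median -0.88, camera adjusted p 0.0583 but under 0.05 without RF1 or RF3, with the replicate block or with the filter of 5 CPM, limma) were led by CIDEC and CIDEA, which act at lipid droplets in liver as well, and both passed adjusted over the list alone as lower in FF. Cholangiocyte markers (7 tested, median -0.47, camera adjusted p 0.137, limma) had CDH1 at -0.74 ± 0.40 and SCTR, which passed adjusted over the list alone. Stellate cell and fibroblast markers (13 tested, median 0.36, camera adjusted p 0.133 but under 0.05 without FF2, limma) had LUM at 1.28 ± 0.55 and ACTA2 at 0.72 ± 0.32. Hepatocyte markers (16 tested, median -0.03, camera adjusted p 0.983, limma) had the cytochrome CYP2H1 at -1.57 ± 0.47 (-2.18 without FF2) and APOA1 at 1.20 ± 0.43.

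Blood cell markers varied between single hens. Red cell markers (9 tested, median 0.36, camera adjusted p 0.0598 but under 0.05 without FF2, RF1 or RF2, limma) had RHAG at 2.03 ± 0.66 (2.72 without FF1 and 0.85 without FF2) and TFRC at 0.47 ± 0.32. Their mean in RF3 stood -0.90 from the mean of the 5 hens on the log2 scale. Heterophil and granulocyte markers (7 tested, median -0.99, camera adjusted p 0.0633 but under 0.05 without RF3, with the replicate block or with the filter of 5 CPM, limma) had 1 member higher and 1 lower adjusted over the list alone. The higher one was the defensin GAL1 (5.30 ± 1.37, 6.29 without FF1 and 0.23 without FF2), at 209 CPM in FF2 and at most 3.82 in each other hen, and the lower one was RSFR (-0.99 ± 0.27). Macrophage markers (13 tested, median -0.40, camera adjusted p 0.247, limma) had PTPRC at 0.65 ± 0.33 and HAVCR1 at -0.48 ± 0.27. T and NK cell markers (16 tested, median 0.23, camera adjusted p 0.188 but under 0.05 without RF2, limma) had CD8B at 1.54 ± 0.57 and IL2RG at -0.68 ± 0.31. B and plasma cell markers (9 tested, median -0.27, camera adjusted p 0.664, limma) had IGLL1 at -1.59 ± 0.62 (-2.24 without FF1) and POU2AF1 at -0.78 ± 0.58 (-0.09 without FF1 and -1.89 without FF2). Thrombocyte markers (8 tested, median -0.30, camera adjusted p 0.459, limma) had ITGB3 at -0.79 ± 0.64 (-1.69 without FF1 and -0.06 without RF2). Muscle markers (4 tested) had ACTA1 at 1.15 ± 0.50 (0.53 without FF1) and TPM1 at 0.43 ± 0.28. Pancreas and gut markers (4 tested) had AMY1A at -0.31 ± 0.33 and AMY2A at -0.52 ± 0.66 (0.09 without FF1 and -1.28 without FF2), and both lists were too small for the list test.

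Across all lists, BUB1 was the 1 member to pass over all genes by the edgeR quasi-likelihood test. Adjusted over the list alone, 11 lists had members that passed. These were 33 passes, with CIDEC and CIDEA counted in each list that holds them, and error across lists was not controlled. Of the 38 lists tested by camera, 3 passed, and with an estimated correlation 0 passed (1 at an unadjusted p under 0.05), the lowest adjusted p being 0.584 (limma). Fry in limma, which asks whether the genes of a list move on balance one way, called 0 lists (6 at an unadjusted p under 0.05, lowest adjusted p 0.157), and its mixed test, which asks whether they change in either direction, called the cholesterol list with adjusted p = 0.00595. Median, mean and test differed in sign for 6 lists: lipoproteins and lipid transport, gluconeogenesis and glycogen, thyroid hormone, bile acids and sterol handling, amino acid catabolism and uric acid synthesis, and hepatocyte markers.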

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

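The setting that left BUB1 out of the cell cycle list was chosen after the data were seen, and all others were planned. With 2666609 to 4622392 counts per hen and 2 hens in FF, 14.6% of genes changed 2-fold were recovered in the simulated data, so changes of that size were mostly not detectable. Larger changes could be missed as well where hens varied more than the simulated ones. BUB1 and AACS kept their direction in all 17 alternatives, and passed in 14 and 13 of them. The threshold of 0.1 and the added limit on the fold change reuse the main fit, so both genes had to pass there. Against 2 genes in the main test, 6 passed without a low-count filter (4 higher and 2 lower in FF), 1 with at least 5 CPM in 2 libraries (1 higher), 79 by DESeq2 (31 higher and 48 lower), 76 by the edgeR likelihood ratio test (30 higher and 46 lower) and 7 at a threshold of 0.1 (5 higher and 2 lower), and limma-voom called 3 (2 higher, BUB1 and AACS, and 1 lower). The causes of these differences were not tested. The likelihood ratio test differs from the main one in not carrying the uncertainty of the dispersion. Leaving out 1 hen gave 0 to 8 genes, 0 to 5 of them higher and 0 to 3 lower in FF. They were 8 without RF3 (THRSP, BUB1, FASN, CPT1A, FBF1, G0S2 and AACS among them) and 6 without FF1 (GAL1, INHBA, BUB1, AACS, KIFC1 and C10ORF58), where FF2 remained as a lone hen assumed to vary like the RF hens. Scaling changed no call, though library totals alone moved the median log2 fold change of all genes by 0.10. Of 1537 single-gene values, nearly all of them from genes not called in the main test, 1448 stayed on their side of the threshold with their direction. A further 70 passed that had not, 7 no longer passed and 12 changed sign without having been called. The 12 belong to 9 genes, among them ACLY, AMY2A, APOB, ESR1, PDK3, PER2, SREBF1 and VTG1.

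Against 3 gene lists called, 0 were called with an estimated correlation, 0 by fry, 6 with the stricter filter and 0 to 10 when 1 hen was left out (0 without FF1, 9 without FF2, 10 without RF1, 7 without RF2 and 8 without RF3). The correlation between genes estimated from these hens was 0.332 for cell cycle and 0.203 for fatty acid synthesis, above the preset 0.01. For cholesterol synthesis and uptake it was -0.0243. The calls of cell cycle and fatty acid synthesis thus rest on a preset below the estimate. A higher estimate cannot be the only reason for lost calls, since lists estimated below the preset weakened too. With the estimate, the unadjusted camera p (limma) went from 1.98e-04 to 0.0288 for cholesterol synthesis and uptake. For endothelial markers it went from 0.0107 to 0.0768, and for the growth hormone list from 0.0140 to 0.0750. Other causes were not tested. The 3 lists were among those called without FF2, RF1, RF2 or RF3. Of the uncalled lists 13 were called in 1 or more alternatives, most often adipocyte markers, endothelial markers, and fatty acid oxidation and ketogenesis, each as lower in FF in 4 of them. Without BUB1 the cell cycle list had a camera adjusted p of 0.000354 (limma). With the replicate number as a block, 6 genes passed (5 higher and 1 lower in FF) and 9 lists. The numbers mark different hens, so the block is not a pairing of hens. Only 2 of them are in both groups, and RF3 is alone in its block. The block fit therefore takes the feeding difference from the other hens, and is not independent of the setting without RF3. Deviations of same-numbered hens from their group means correlated at -0.143 and -0.355 across genes. With 2 FF hens these deviations mirror each other, so the correlations cannot tell whether equal numbers share a pen or day.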

Other observations

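The tests of other splits of the hens, of a mixture in RF3 and of the FF hens with RF3 counted as FF were chosen after the result was seen. Those of a wrong label on RF3 and of cAMP-responsive genes were chosen before their own results, though the patterns that prompted them had been seen. Several immediate targets and partners of cyclic AMP signalling lay lower in FF than in RF, all picked after their values were seen. SIK1, a kinase induced by cyclic AMP, was at 32.7 ± 12.9 CPM (SD, n = 2) in FF and 371 ± 238 CPM (SD, n = 3) in RF (log2 fold change -3.51 ± 0.63, -2.86 without RF3). The transcription factor gene CREM lay at -1.89 ± 0.52 and the phosphodiesterase PDE4B at -1.93 ± 0.52 (-2.53 without FF1), beside PCK1 at -2.83 ± 0.72 and PPARGC1A at -2.26 ± 0.70. None passed the edgeR quasi-likelihood test (adjusted p from 0.146 for SIK1 to 0.436 for PPARGC1A), and by DESeq2 all but PPARGC1A had an adjusted p under 0.05. A hypothesis is that cyclic AMP drove less transcription in the FF livers, but of a list of 18 other genes known to respond to cyclic AMP 7 were tested, 5 of them above 0, and camera in limma gave an unadjusted p of 0.302 in the higher direction, which leaves the question open.

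Single hens held further differences, of which KIFC1, C10ORF58 and HBAA were picked after their values were seen. GAL1 (FF2 at 209 CPM) was one, and KIFC1 was another, at 3.64 CPM in FF2 against 49.1 to 70.2 in the other 4. C10ORF58 was listed at 0 in FF2 and lay between 66.1 and 145 CPM in the others. The globin gene HBAA was at 566 CPM in RF3 and between 1471 and 2146 CPM elsewhere. BUB1 stood out from its own list, with a log2 fold change of 4.70 where no other tested member exceeded 1.53. Its FF mean of 106 CPM compares with at most 58.8 CPM for any other tested member. That member was E2F1, named after its values were seen, which was not higher in FF (65.1 CPM in RF).

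RF3 lay near the FF hens in several fatty acid synthesis genes and in some other genes, and its THRSP, SCD and ME1 values were 7524, 7200.4 and 460.4 CPM, near those of FF, while it had the lowest G0S2 (6.78 CPM) and the highest IGFBP1 (438 CPM) of all 5 hens. If RNA of an FF liver had been mixed into RF3, one share should serve all genes. Of the 16 tested fatty acid synthesis genes, the 9 at least doubled in FF over RF1 and RF2 were used. They include the paralogues THRSP (100%) and THRSPB (163%), whose values are uncertain. The median share needed was 77.5% for these 9 genes and 22.3% for 22 other genes higher in FF. These medians lay 55.2 percentage points apart (95% bootstrap interval 12.2 to 102), and single genes ranged widely (14.8% to 163% and -6.68% to 349%). The fatty acid synthesis genes had prompted the test, and the interval covers spread over genes and not between hens. The medians thus show unequal shares for this pattern but cannot decide on a mixture. Were none of the RF3 transcripts its own, 17 of the 22 other genes would still have room for less than 77.5% (5 for as much or more), taking the lower FF hen. The comparison of medians replaced a first one, which asked whether the median of the other genes lay below the lowest share of any fatty acid synthesis gene (14.8%, FADS2) and left the matter open. Each hen was also placed between the other RF hens (0) and the FF hens (1), over the 50 genes that best part the other 4 hens. RF3 lay at 0.484 (95% bootstrap interval 0.401 to 0.593), below the 0.75 set beforehand for a mislabelled hen. Left out in their turn, RF1 and RF2 lay at 0.153 and -0.0123. FF1 and FF2, left out in their turn, lay at 0.223 and 0.674, so hens labelled FF also fell below 0.75. With RF3 counted as FF, FF1 and FF2 lay higher than RF3, at 0.7004 (interval 0.594 to 0.938) and 0.948. As the FF positions depended on where RF3 was counted, a choice made after the result, they cannot decide on a wrong label. A difference in feed intake or time since feeding is left open too, untested.

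With 5 hens there are 10 splits into 2 and 3, too few for a share under 0.05. By the edgeR quasi-likelihood test the real split called 2 genes and the highest other split 1, so that 1 of 10 splits, the real one, gave as many. By DESeq2 the real split called 79 and again 1 of 10 gave as many, the highest other split being 70 (RF1 and RF2 against the rest). At an unadjusted p under 0.05 by edgeR, 2 of 10 splits, the real one included, gave as many as the real one, with 403 in the real split and 415 for FF2 and RF3 against the rest.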
